A study of Mus musculus with 40 samples.

How the data were processed

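Total RNA of cerebellum, cerebrum, heart and liver was taken from 10 adult mt-Keima mice, which carry a pH-sensitive fluorescent protein in their mitochondria as a reporter of mitophagy. Per the labels, 5 mice were exposed to whole-body gamma irradiation (6 Gy at 0.74 Gy per min) and 5 were placed in the irradiator without exposure (sham), and all were killed 48 h later. Each mouse gave 1 array per tissue, 40 arrays in all, and the mice were 8 or 9 months old and of both sexes. The sham group held 2 males and 3 females and the irradiated group 3 males and 2 females. The same 10 mice were used for all 4 tissues, so the tissues are not independent samples of the 2 groups.

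Per the labels, Cy3-labelled cRNA was made from 200 ng of total RNA and hybridised to 1-colour Agilent arrays. Per the file headers, the arrays were scanned on an Agilent G2600D scanner and read with Feature Extraction 12.0.3.1, with a probe layout built on mm9. The deposited scanner files hold the intensity of each spot after the scanner software's own background subtraction, with no normalization between arrays. An array had 62976 spots, of which 59305 were not controls and held 56605 probes. No spot was saturated on any array. The deposited value table of the whole series holds 1 column per sample in an arbitrary score. Set against the scanner files, each of its 40 columns had the ranks of log2 intensity of 1 array, the same set of values as every other column, a median of -0.19 and an SD of 1.00. Those are the marks of quantile normalization followed by scaling to unit SD on each array, a step that no label or header records; the direction of the scores followed intensity, and their scale in log2 units is unknown.

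The value table also showed which array belonged to which sample. In cerebellum and cerebrum each column matched the scanner file of its own sample. In heart and liver each column matched the scanner file attached to the sample of the other tissue with the same group and replicate (Spearman correlation at least 0.9999 over probes, against 0.816 to 0.855 for the sample's own file), so the scanner files of 20 samples were exchanged between these tissues. The arrays were therefore joined to samples through the value table. After the join, albumin (Alb) had a mean log2 intensity of 18.27 on liver arrays and 8.12 on heart arrays, alpha myosin heavy chain (Myh6) one of 5.11 and 18.45, and the sex-linked genes matched the labelled sex on 40 of 40 arrays. The join moves arrays between tissues and not between sham and irradiated mice. Results with the files as attached are given as an added alternative.

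The scanner files give probes by accession and no gene name. Accessions were matched without versions to RefSeq gene names of GRCm38.p6, which gave 1 symbol to 32994 probes (22911 genes, 7899 of them with several probes). The other 23611 probes have no name here and were left out of the gene counts. No coordinates are given, because the layout and the names come from different builds.

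Intensity was log2-transformed and each array's 75th percentile over all probes that are not controls was subtracted. Spots of 1 probe were averaged, and spots marked as outliers by the scanner software were left out. A probe was tested in a tissue where it was well above background on at least 4 arrays of that tissue, whatever their group. The brightest such probe stood for its gene. Of the called genes, 4 in cerebellum, 3 in cerebrum, 13 in heart and 24 in liver had several measured probes, and none had a probe that moved the other way. Sizes could differ by over 1.5 times between probes, as for Trp53inp1 (1.48 and 0.75) and Slc25a37 (-2.14 to -0.71) in heart and Btla (-4.12 and -2.26) and Polk (1.15 to 0.65) in liver. A gene counts as above background on an array where any of its probes is. Where a gene was not well above background on any array of a group, its fold is written as "at least N-fold". That bound compares the mean of the brighter group with the mean, over the arrays of the dim group, of the higher of the dim probe's own signal and the lowest signal among probes well above background. No bound is given where it falls under 1.

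Irradiated and sham arrays were compared within each tissue with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with sex as a covariate. Every adjusted p of a gene is limma's with Benjamini-Hochberg adjustment over the genes tested in that tissue, and 0.05 was the threshold. Errors of log2 changes are SE and those of group means are SD. The labels mark the array of irradiated heart replicate 1 as not included, so it was left out and put back as an alternative. Genes whose response differed between tissues were found with limma's F test on 1 fit over the 4 tissues, over the genes measured in at least 1 tissue and with 1 probe per gene, the brightest over all tissues, with a sex term per tissue and the animal as a random block (estimated correlation 0.0223). A sex by irradiation interaction was tested in each tissue. Single values, which are Spata18 and the mean of the p53 target list, were also tested with 2-sided exact permutation tests.

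A set of 57 lists of pathway genes and cell type markers was fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. A list was tested where at least 5 members were measured, with limma's camera at a preset correlation of 0.01 between members, and the p-values of all 228 pairs of list and tissue were adjusted together. Camera asks whether a list's members moved relative to the other genes. Camera with the correlation estimated from the data was an alternative. Adjusted p-values of lists are camera's unless another test is named.

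The rule for named genes took, in each tissue, Spata18 and 8 p53 target genes whatever their p, the 10 largest rises and 10 largest falls past the threshold with clone and predicted names left out, up to 4 members with the smallest p of each called list, and mitophagy genes past the threshold. Across tissues it took up to 15 genes called in the same direction in all 4 and the 10 genes with the smallest p of the F test. A part of those genes is described, and some are not reported here.

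The arrays lay on 5 slides of 8. Slide 1 held all cerebellum sham arrays and 3 irradiated ones, and slide 2 the other 2 together with 5 sham and 1 irradiated cerebrum arrays. Slide 3 held 4 irradiated cerebrum and 4 sham liver arrays, slide 4 held 1 sham and 5 irradiated liver and 2 sham heart arrays, and slide 5 the rest of the heart arrays. Slide and treatment overlapped in part in every tissue, and slide 5 held the compared groups in separate rows. Each result was therefore refitted with slide as a block and within the 1 slide that held both groups. In cerebrum both fits rest on 1 irradiated array and in liver on 1 sham array, assumed to vary like the rest. Arrays are named by group and replicate, so sham 3 is replicate 3 of a tissue's sham group.

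The number of arrays and their signal over background limit the precision. The array left out was the dimmest, with a 75th percentile of intensity of 405 against 766 or more on the others. The share of probes well above background was 70.1% to 77.1% in cerebellum, 66.9% to 77.5% in cerebrum, 51.9% to 64.0% in liver and 47.0% to 63.2% in heart. The fits were tested on simulated data built on the real arrays, with 50 genes changed at each fold. Of genes changed 2-fold, 82% were recovered in cerebellum, 78% in cerebrum, 36% in heart and 56% in liver, and of genes changed 4-fold 98%, 98%, 86% and 94%. A simulated list shifted by 0.5 was found in every tissue, and of 100 lists with no shift 2, 4, 0 and 1 passed an unadjusted p of 0.05 in cerebellum, cerebrum, heart and liver. The simulated noise was independent between genes, so these counts cannot show how camera behaves where list members vary together. Of genes whose simulated response differed 4-fold between tissues, 76% were recovered.

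Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone and the authors' deposited scores in place of the main scaling. Others were no filter on dim probes or only probes above background on every array, the mean of a gene's probes, no sex covariate, sex with age, the replicate number as a block, slide as a block, the arrays of 1 slide, 1 fit of all tissues with slide, eBayes without the trend, array weights and leaving out each array in turn. The mean signal that normexp normally takes was replaced by the median signal, which is the one used here. Alternatives added after the data were examined were unnamed probes tested too, scanner files as attached, and leaving out the arrays that carried transcripts of another tissue.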

Results

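Gene expression was measured on 40 single-colour Agilent arrays, 1 per mouse and tissue, in the cerebellum, cerebrum, heart and liver of 5 sham-treated and 5 irradiated mice. The irradiated mice had received 6 Gy of whole-body gamma rays 48 h earlier. The 75th percentile of array intensity ran from 2645 to 3795 in cerebellum, 2241 to 3295 in cerebrum, 1232 to 1660 in liver and 766 to 1405 in heart. The array of irradiated heart replicate 1 was left out, as its label asks, which leaves 5 sham and 4 irradiated arrays in heart and 5 of each elsewhere. The comparison asks which transcripts a DNA-damaging dose changes in each tissue, and whether Spata18, a gene linked to clearance of damaged mitochondria, is among them. Changes are log2 of irradiated over sham with SE. Most results are followed by a slide-blocked value and a within-slide value, the latter from the arrays of the 1 slide that held both groups. In cerebrum both rest on irradiated 1 and in liver on sham 5, so a call there tests 1 array of that group.

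At an adjusted p of 0.05, 13 of 17985 genes changed in cerebellum (3 higher, 10 lower), 10 of 17834 in cerebrum (4 higher, 6 lower), 77 of 15390 in heart (12 higher, 65 lower) and 94 of 15840 in liver (38 higher, 56 lower). Slide-blocked fits called 10, 0, 42 and 47 genes, and within-slide fits 9, 0, 27 and 51. In cerebrum 1 irradiated array shared a slide with sham arrays, so these fits test little there. Leaving out 1 array moved the count in cerebellum to 34 (without irradiated 1) and 20 (without irradiated 4), and in liver to 56 (without irradiated 2). In heart the count was 50 without sham 1, 46 without sham 4, 47 without irradiated 3, 47 without irradiated 5 and 331 without irradiated 2. Of the 57 gene lists, 10 were called in cerebellum, 19 in cerebrum, 13 in heart and 22 in liver. In cerebellum 16 lists were called without sham 3 and 5 without irradiated 4. With an estimated correlation between members only the B cell and p53 target lists in liver were called, each at an adjusted p of 0.0365.

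**Figure D1:**
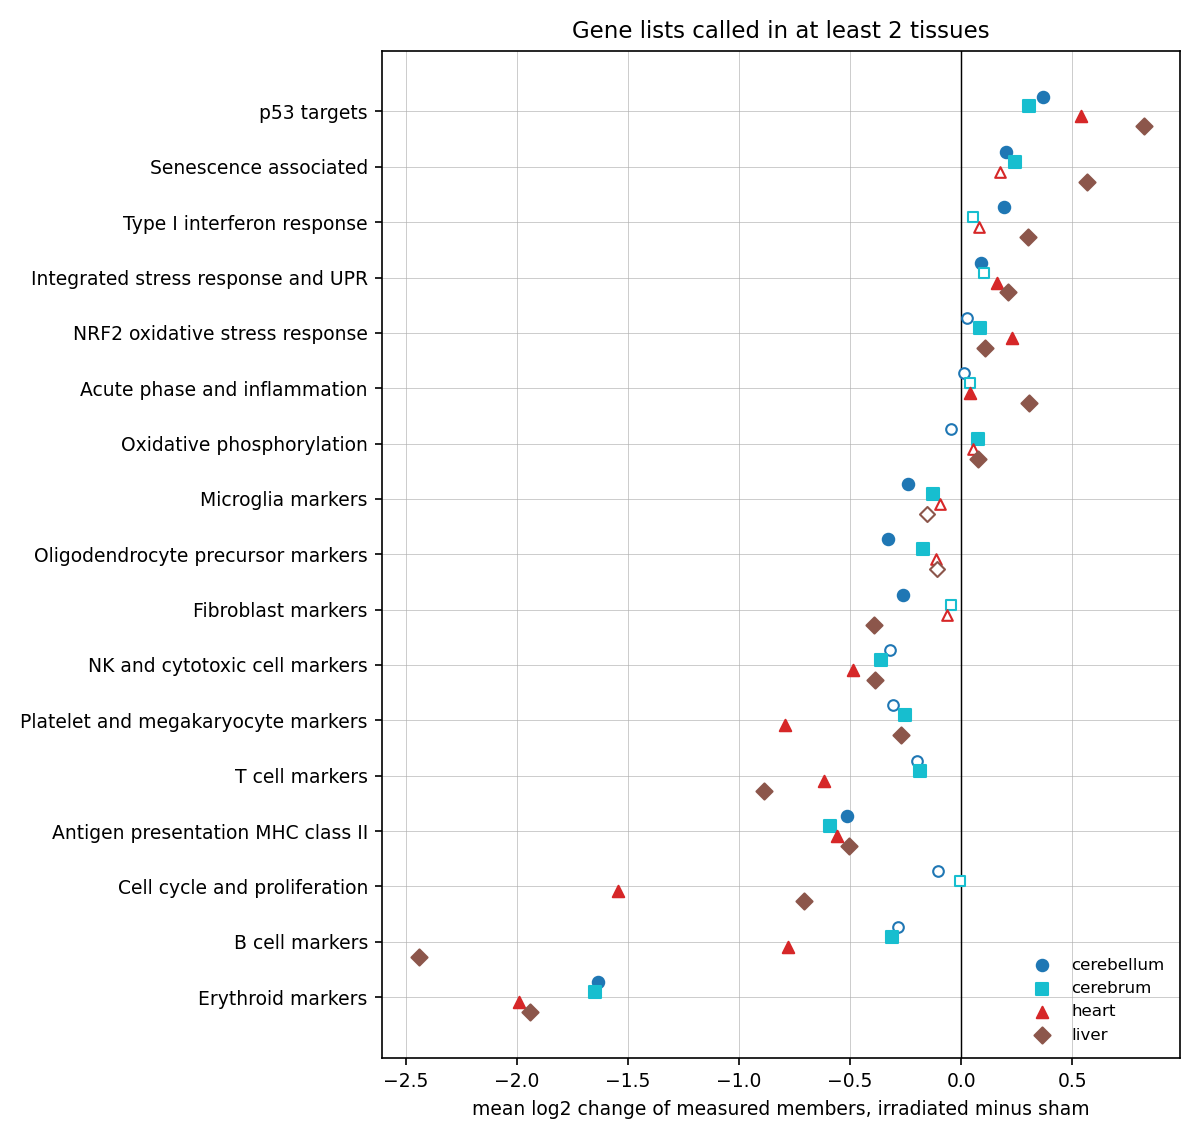
Mean log2 change (irradiated over sham) of the measured members of gene lists in each tissue, where filled symbols are lists called at a preset correlation and open symbols are lists not called. The p53 target list lies at 0.37 in cerebellum, 0.31 in cerebrum, 0.54 in heart and 0.82 in liver, and the erythroid list at -1.63, -1.65, -1.99 and -1.94.

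The alpha globin genes Hba-a1 and Hba-a2, the beta globin genes Hbb-b1, Hbb-b2 and Hbb-bt, and Alas2, which makes the first enzyme of heme synthesis in erythroid cells, fell in all 4 tissues. They were the 6 genes of the 14153 measured everywhere to do so, where independent lists would share 4.61e-08. Hba-a1 changed by -4.56 ± 0.30 in cerebellum (adjusted p = 9.38e-05, 23.5-fold lower), -4.69 ± 0.35 in cerebrum (adjusted p = 0.000782), -4.54 ± 0.20 in heart (adjusted p = 3.98e-07) and -5.48 ± 0.21 in liver (adjusted p = 6.54e-08). The fall of Hbb-bt was 60.5-fold in cerebellum (-5.92 ± 0.50, adjusted p = 0.00056), 81.1-fold in heart (-6.34 ± 0.20, adjusted p = 3.47e-08), -5.78 ± 0.60 in cerebrum (adjusted p = 0.00315) and -7.64 ± 0.45 in liver (adjusted p = 2.71e-06). Globin copies are nearly identical in sequence, so which copy a probe measured is uncertain. Alas2 changed by -6.46 ± 0.57 in cerebellum, -5.70 ± 0.46 in cerebrum and -7.09 ± 0.32 in heart (adjusted p = 0.000786, 0.000782 and 3.98e-07), where it was well above background on 3 of 5, 4 of 5 and 2 of 4 irradiated arrays. In liver its change was -2.20 ± 0.43 (adjusted p = 0.0446), and the call there was lost without sham 3 or 5 or without irradiated 1, 2, 4 or 5 (-2.31 to -1.90, adjusted p = 0.0791 to 0.204).

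Slide-blocked and within-slide changes of Hba-a1 were -4.50 and -4.44 in cerebellum, -4.33 and -4.35 in heart and -5.29 and -5.45 in liver, all past the threshold. Those of Hbb-bt were -5.88 and -5.74 in cerebellum, -6.08 and -6.08 in heart and -7.41 and -7.96 in liver, also past it. In cerebrum the slide-blocked values of the 6 genes were -7.21 to -5.05 and the within-slide values -6.89 to -4.87, not called. In liver Hbb-b1 was at -7.28 within the slide (not called) against -7.58 ± 0.65 in all arrays. Alas2 was at -2.06 with slide as a block (not called) and -2.82 within the slide (called). The erythroid list as a whole held 20 to 22 measured members, of which 6 fell in cerebellum, cerebrum and liver and 8 in heart, and 8, 8, 7 and 9 fell adjusted over the list alone in cerebellum, cerebrum, liver and heart. Its mean was -1.63, -1.65, -1.94 and -1.99 and its median -0.21, -0.28, -0.15 and -0.41 in that order (adjusted p = 1.32e-09, 1.09e-11, 4.17e-12 and 1.28e-18). With an estimated correlation the adjusted p was 0.18, 0.0552, 0.144 and 0.0552. Markers of platelets, which also circulate in blood, had list means of -0.25 in cerebrum, -0.79 in heart and -0.27 in liver (adjusted p = 0.0223, 0.00203 and 0.0266; 0.311, 0.676 and 0.676 with an estimated correlation). None of their members passed the test alone, and with 2 genes at their bound the mean in heart was -0.62 and the median -0.41, against a median of -0.56. The platelet call was lost in cerebrum without sham 2, irradiated 2 or irradiated 5 (-0.22 to -0.20) and in liver without sham 2 or 4 or irradiated 2 (-0.28 to -0.15). It was kept in heart without sham 2 (-0.46) and in liver without sham 1 (-0.41). Its slide-blocked means were -0.25 in cerebrum (adjusted p = 0.209), -0.35 in heart (adjusted p = 0.0913) and -0.04 in liver (adjusted p = 0.995), and its within-slide means -0.14, -0.45 and -0.25 (adjusted p = 0.716, 0.0218 and 0.43).

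**Figure D2:**
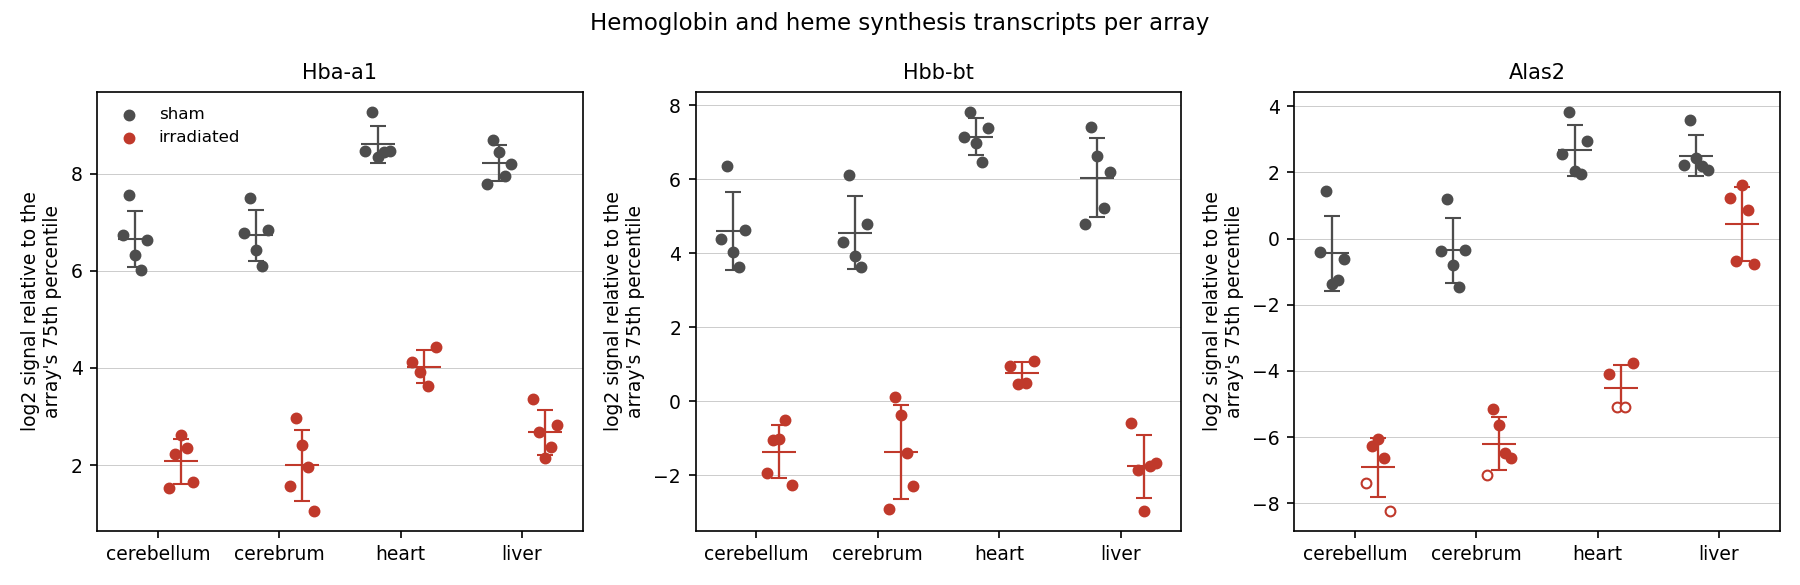
Normalised log2 intensity of globin genes and Alas2 on each sham and irradiated array of the 4 tissues, with filled points well above background, open points not, bars at the mean and whiskers of 1 SD. Hba-a1 lies lower on every irradiated array than on every sham array of its tissue, with changes of -4.56 in cerebellum, -4.69 in cerebrum, -4.54 in heart and -5.48 in liver.

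In cerebellum, 5 irradiated against 5 sham arrays, a small set of p53 target genes rose. Eda2r, a receptor of the tumour necrosis factor family, was not well above background on any sham array and was at least 10.5-fold higher after irradiation (4.26 ± 0.36, adjusted p = 0.00056). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.88-fold (1.53 ± 0.15, adjusted p = 0.00118) and Dcxr, a dicarbonyl and xylulose reductase, 1.83-fold (0.87 ± 0.10, adjusted p = 0.00421). Of 35 measured p53 targets these 3 rose and 32 did not pass, among them Trp53inp1 (0.50 ± 0.12, adjusted p = 0.27), Gdf15 (1.07 ± 0.29, adjusted p = 0.365), Bax (0.24, adjusted p = 0.555) and Mdm2 (0.13, adjusted p = 0.841). Adjusted over the list alone, 11 rose and 1 fell. The list had a mean of 0.37 and a median of 0.13 (0.34 and 0.13 with Eda2r at its bound; adjusted p = 5.01e-10, and 0.0751 with an estimated correlation), slide-blocked 0.34 and within-slide 0.23. Slide-blocked and within-slide values were both 1.58 for Cdkn1a and 0.91 for Dcxr (adjusted p = 0.0235 and 0.0688). Eda2r was slide-blocked at 4.36 (adjusted p = 0.00734) and too dim for the within-slide mean.

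The lists of oligodendrocyte precursor and microglia markers were called lower in irradiated cerebellum. Gpr17, a receptor of maturing oligodendrocyte precursors, fell 2.37-fold (-1.24 ± 0.18, adjusted p = 0.0423; slide-blocked -1.51, within-slide -1.50, both called). Its call was lost when any single array other than irradiated 4 was left out (-1.36 to -1.13, adjusted p = 0.0502 to 0.218). In the precursor list 17 of 19 measured members had a negative change, 1 fell over all genes and 2 fell adjusted over the list alone. The mean was -0.33 (adjusted p = 0.000106; 0.439 with an estimated correlation), slide-blocked -0.38 and within-slide -0.38, with Neu4 at -0.76 ± 0.20 (adjusted p = 0.36). In the microglia list 14 of 18 members were negative and 0 passed in limma, over all genes or adjusted over the list alone. The list mean was -0.24 (adjusted p = 0.000122; 0.631 with an estimated correlation), slide-blocked -0.24 and within-slide -0.24, and -0.14 without sham 2 (adjusted p = 0.00191), which stood above the other sham arrays for this list and the next. The list of MHC class II genes, which present antigen, had a mean of -0.51 over 9 members, with Cd74 at -1.39 ± 0.41 (adjusted p = 0.415). None passed over all genes and 2 fell adjusted over the list alone. That list was called at an adjusted p of 0.00391 (0.608 with an estimated correlation) but not without irradiated 4 (-0.47, adjusted p = 0.0592), with slide as a block (-0.46, adjusted p = 0.0959) or within the slide (-0.48, adjusted p = 0.0742), and was at -0.36 without sham 2.

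Gsk3b, a kinase of glycogen metabolism and Wnt signalling, was 1.56-fold lower in irradiated cerebellum (-0.64 ± 0.08, adjusted p = 0.0135), though its 3 probes ranged from -0.64 to -0.00249. It was at -0.68 in both slide fits (adjusted p = 0.0524 and 0.107), and its call was lost without sham 1, 2 or 5 or irradiated 2 or 5 (-0.65 to -0.61, adjusted p = 0.0503 to 0.0946). The type I interferon response list had a mean of 0.19 (adjusted p = 0.000135; 0.631 with an estimated correlation; slide-blocked 0.22, within-slide 0.24). Its mean was 0.12 without sham 3, 0.13 without irradiated 1, 0.06 without irradiated 2 and 0.31 without irradiated 3, called each time. Of its 27 members 24 were positive, such as Ifit3 at 0.48 (adjusted p = 0.604), and 0 passed in limma. Lists of the circadian clock (0.11), the integrated stress response (0.09), fibroblasts (-0.26) and senescence (0.20, median 0.01) were called at adjusted p-values of 0.0237 to 0.0497 (0.428 to 0.713 with an estimated correlation). None of these 4 kept its call in both slide fits except the fibroblast list (-0.40 and -0.40), and each lost it on leaving out 1 array. Those arrays were sham 1 and irradiated 1 and 4 for the clock (0.05 to 0.11) and sham 4 and irradiated 1 and 4 for the stress response (0.01 to 0.07; 0.14 without irradiated 2). They were sham 1, 2 and 4 and irradiated 1 and 4 for fibroblasts (-0.31 to -0.16), and sham 4 and 5 and irradiated 2 and 4 for senescence (0.14 to 0.20).

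In cerebrum, again 5 against 5 arrays, 4 genes rose and the 6 erythroid genes were the only ones to fall. Ephx1, the microsomal epoxide hydrolase, rose 1.98-fold (0.98 ± 0.09, adjusted p = 0.00203) and Cdkn1a 2.97-fold (1.57 ± 0.15, adjusted p = 0.00222). Dcxr rose 1.87-fold (0.91 ± 0.09, adjusted p = 0.00311) and Trp53inp1, a p53-induced stress gene, 1.72-fold (0.78 ± 0.11, adjusted p = 0.0361; 0.22 at its other probe). Of 35 measured p53 targets, Cdkn1a, Dcxr and Trp53inp1 rose and 32 did not pass, while 12 rose adjusted over the list alone. Among the others were Eda2r at 3.51 ± 0.65 (adjusted p = 0.202), Gdf15 at 1.07 ± 0.20 (adjusted p = 0.202) and Mdm2 at 0.10. The p53 list had a mean of 0.31 and a median of 0.11 (adjusted p = 1.23e-08; 0.0552 with an estimated correlation), slide-blocked 0.33 and within-slide 0.26. Slide-blocked and within-slide changes of Ephx1 (0.95 and 0.94), Cdkn1a (1.74 and 1.94), Dcxr (0.84 and 0.80) and Trp53inp1 (0.85 and 0.84) were of like size and none passed (adjusted p = 0.12 or more). Eda2r was called without irradiated 5 (2.58, adjusted p = 0.012), and Trp53inp1 lost its call without any 1 array other than irradiated 4 and 5 (0.69 to 0.80, adjusted p = 0.07 to 0.159). The cerebellar gene Pcp2 was high on sham 5 (2.05) and irradiated 4 (2.42), against -2.27 to -1.92 on the other cerebrum arrays. Without these 2 arrays Hbb-bt (-5.86), Trp53inp1 (0.81) and Dcxr (0.93) were not called (adjusted p = 0.0578, 0.19 and 0.0511), nor the oligodendrocyte (-0.03), T cell (-0.18) and senescence (0.27) lists.

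Several groups of glial and immune genes were lower in irradiated cerebrum, by small amounts and with no member past the threshold over all genes. Precursors of oligodendrocytes had a list mean of -0.17 with 17 of 19 members negative (adjusted p = 5.43e-05; slide-blocked -0.21, within-slide -0.24). The MHC class II mean was -0.59 with 8 of 9 members negative (adjusted p = 0.000106), and 5 fell adjusted over the list alone. It fell short of the threshold with slide as a block (-0.39, adjusted p = 0.115) and within the slide (-0.22, adjusted p = 0.422). Microglia markers had a mean of -0.13 with 16 of 18 members negative (adjusted p = 0.000587; slide-blocked -0.21, within-slide -0.24). Csf1r, the receptor that keeps microglia alive, was at -0.45 (adjusted p = 0.242), and the list was not called without sham 4 (-0.07, adjusted p = 0.0588). With an estimated correlation these 3 lists had adjusted p-values of 0.311, 0.311 and 0.479. Markers of the choroid plexus, which makes cerebrospinal fluid, had a mean of -0.87 (adjusted p = 0.000106; 0.631 with an estimated correlation), with Ttr at -1.96 (adjusted p = 0.784) and Kcne2 at -2.10 (adjusted p = 0.782). Without irradiated 3 the mean was -0.58. Their direction turned in both slide fits (0.62 and 0.40, called higher at adjusted p = 7.49e-05 and 1.81e-06), as did that of mature oligodendrocyte markers (-0.10, adjusted p = 0.0223, and 0.781 with an estimated correlation; slide-blocked 0.22 and within-slide 0.13, called higher at 2.75e-05 and 0.00627). The oligodendrocyte list also lost its call without sham 4 or irradiated 4 (-0.03 for each) and was at -0.16 without irradiated 1.

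Markers of natural killer cells (-0.36), neutrophils (-0.53), monocytes (-0.18), T cells (-0.19), B cells (-0.31) and exocrine pancreas (-0.29) were also called lower in cerebrum, at adjusted p-values of 0.000292 to 0.0478 (0.311 to 0.479 with an estimated correlation). Of these only the monocyte list was called in both slide fits (-0.42 and -0.37), which rest on irradiated 1, an array low for it (-1.05 against -0.81 to -0.72 on the other 4), and the pancreas list turned (0.05 and 0.13). The natural killer mean was -0.17 without irradiated 2 (adjusted p = 0.00497) and the neutrophil mean -0.35 without sham 2 (adjusted p = 0.00834), both still called. The T cell call was lost without sham 1 or 2 or irradiated 1, 2 or 4 (-0.19 to -0.14) and the B cell call without sham 2 or 4 or irradiated 1, 3 or 5 (-0.34 to -0.18). The pancreas call was lost without sham 2 or 4 or irradiated 2, 3, 4 or 5 (-0.30 to -0.20). Lists with a positive mean were those of oxidative phosphorylation (0.08, 40 of 47 members positive), hypoxia (0.14, 16 of 18), the NRF2 oxidative stress response (0.09, 17 of 19, of which Ephx1 rose), senescence (0.24, of 13 members Cdkn1a rose) and mitophagy. Their adjusted p-values were 0.000962 to 0.0378, and 0.336 to 0.799 with an estimated correlation. The oxidative phosphorylation list was not called with slide as a block (0.02), within the slide (-0.02), without sham 3 (0.03) or without irradiated 5 (0.05), and the senescence list was not called without sham 1 or 4 or irradiated 1 or 2 (0.20 to 0.26) but was called in both slide fits (0.28 and 0.31). Hypoxia was called in neither (0.07 and 0.06, adjusted p = 0.34 for both) and NRF2 with slide as a block only (0.05 in both, adjusted p = 0.0191 and 0.0757), with 0.06 without irradiated 2.

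In heart, 5 sham against 4 irradiated arrays, genes of dividing cells fell together. Mki67, the standard marker of proliferation, changed by -3.57 ± 0.29 and Top2a, a topoisomerase of chromosome segregation, by -4.20 ± 0.34 (adjusted p = 0.000124 for both), the latter well above background on 1 of 4 irradiated arrays. Prc1, a cytokinesis protein, changed by -3.13 ± 0.25 (adjusted p = 0.000124; 1 of 4) and Ccnb2, a mitotic cyclin, by -2.87 ± 0.25 (adjusted p = 0.000166; 2 of 4). Below background on every irradiated array were the histone gene H2ac4, at least 10.4-fold lower (-5.00 ± 0.44, adjusted p = 0.000187), and the replication factor Mcm10, at least 2.48-fold lower (-3.59 ± 0.37, adjusted p = 0.000902). All 37 measured members of the cell cycle list had a negative change. Of these 20 fell and 17 did not pass, and 28 fell adjusted over the list alone. The list mean was -1.54 and the median -1.56, or -1.31 and -1.16 with genes below background at their bound (adjusted p = 1.49e-50; 0.0552 with an estimated correlation), slide-blocked -1.50 and within-slide -1.39. Slide-blocked and within-slide values were -3.46 and -3.48 for Mki67 and -4.15 and -4.14 for Top2a, and Prc1 (-3.0 and -3.02) and Ccnb2 (-2.74 and -2.76) were likewise called in both. H2ac4 and Mcm10 were called with slide as a block (-5.04 and -3.37).

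**Figure D3:**
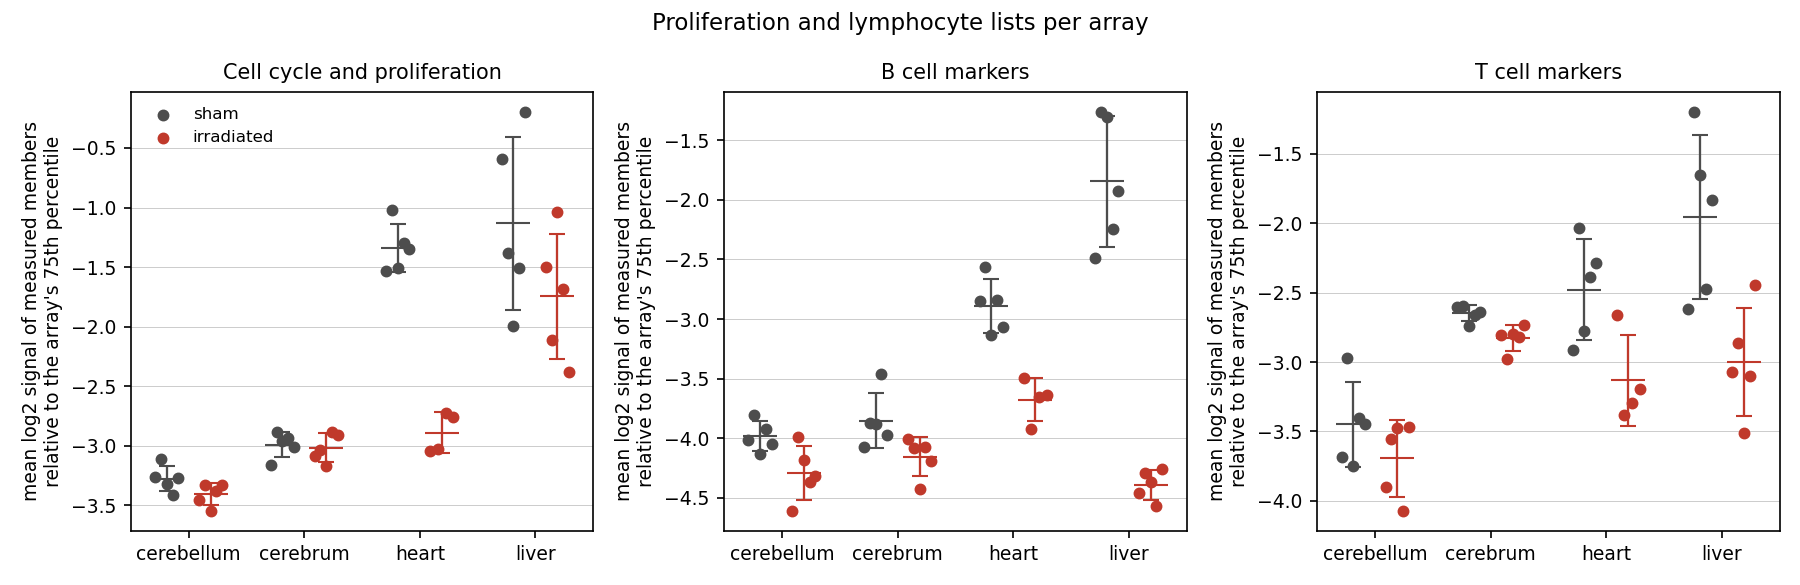
Mean log2 intensity of the cell cycle list and of lymphocyte marker lists on each array, by tissue and group, with bars at the group mean and whiskers of 1 SD. The list changes were -1.54 for the cell cycle in heart, -2.44 for B cells in liver and -0.89 for T cells in liver.

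Among the genes that rose in heart were the p53 targets Eda2r (2.11 ± 0.24, 4.32-fold, adjusted p = 0.00159) and Cdkn1a (1.76 ± 0.23, 3.38-fold, adjusted p = 0.00439). Others were Trp53inp1 (1.48 ± 0.19, 2.78-fold, adjusted p = 0.00428) and Phlda3, an inhibitor of Akt (1.32 ± 0.21, adjusted p = 0.0168). Of 35 measured targets these 4 rose and 31 did not pass, with Bax at 0.92 (adjusted p = 0.0972) and Mdm2 at 0.27 (adjusted p = 0.838), and 11 rose adjusted over the list alone. The list mean was 0.54 and the median 0.42, with 31 members positive (adjusted p = 1.69e-15; 0.0973 with an estimated correlation), slide-blocked 0.52 and within-slide 0.51. Slide-blocked and within-slide values were 2.01 and 1.99 for Eda2r and 1.49 and 1.48 for Cdkn1a, all called. Trp53inp1 was at 1.33 (adjusted p = 0.0328) and 1.32 (adjusted p = 0.0593) and Phlda3 at 1.09 (adjusted p = 0.0847) and 1.05 (adjusted p = 0.0432). The Phlda3 call was lost without irradiated 3, 4 or 5 (1.28 to 1.32, adjusted p = 0.0651 to 0.0688), and Bax was called without sham 2 (1.05, adjusted p = 0.0148) or irradiated 2 (1.03, adjusted p = 0.0392).

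Ces2e, a carboxylesterase, rose 4.26-fold in heart (2.09 ± 0.20, adjusted p = 0.000473; slide-blocked 2.16, within-slide 2.15). The chemokine genes Ccl12 (1.59 ± 0.24, adjusted p = 0.0139), Ccl7 (1.19 ± 0.22, adjusted p = 0.0412) and Cxcl1 (1.27 ± 0.23, adjusted p = 0.0412), which draw monocytes and neutrophils into tissue, rose as well. Ccl12 had a slide-blocked value of 1.73 (adjusted p = 0.0328) and a within-slide value of 1.71 (adjusted p = 0.0763) and was not called without irradiated 5 (1.49, adjusted p = 0.0677). Ccl7 (1.19 and 1.17) and Cxcl1 (1.30 and 1.26) were called in neither slide fit (adjusted p = 0.0923 to 0.301). Ccl7 kept its call only without sham 5 or irradiated 2, and Cxcl1 only without sham 2 or irradiated 2 (otherwise 1.08 to 1.27 and 1.13 to 1.39). In the acute phase list 1 of 17 members rose, and 3 rose adjusted over the list alone. Lcn2 was at 1.23 (adjusted p = 0.0623; called without sham 2, at 1.37, and with slide as a block, at 1.48) and Saa3 at 1.55 (adjusted p = 0.181). That list had a mean of 0.04 and a median of 0.24 (adjusted p = 0.00923; 0.58 with an estimated correlation), slide-blocked 0.51 and within-slide 0.53, and its mean was negative without sham 4 (-0.17) or sham 5 (-0.08) and 0.02 to 0.49 without any other array. The NRF2 list (0.23, adjusted p = 0.00433; slide-blocked 0.38, within-slide 0.35) and the integrated stress response list (0.16, adjusted p = 0.0172; 0.20 in both slide fits) had no member past the threshold (adjusted p = 0.768 and 0.608 with an estimated correlation). The NRF2 list was at 0.36 without sham 2 and not called without sham 5 (0.11), nor was the stress response list without sham 3 (0.11) or irradiated 5 (0.10).

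B and T cell lists were called lower in heart. Fcmr, the IgM receptor of B cells, was below background on every irradiated array and at least 1.61-fold lower (-2.74 ± 0.35, adjusted p = 0.00428; slide-blocked -2.58). Cd79b was at -1.37 (adjusted p = 0.08). Of 12 measured B cell markers 1 fell, and 4 adjusted over the list alone, Fcmr being too dim within the slide. The list had a mean of -0.78 and a median of -0.63, or -0.41 and -0.48 at the bounds (adjusted p = 3.5e-05; 0.269 with an estimated correlation), slide-blocked -0.65 and within-slide -0.23 (adjusted p = 0.229). The T cell list had a mean of -0.62 (adjusted p = 5.43e-05; 0.395 with an estimated correlation; slide-blocked -0.59, within-slide -0.62). Ccr7 was at -1.62 (adjusted p = 0.0878; called without irradiated 2, at -1.90), and 1 of 15 members fell adjusted over the list alone. Natural killer (-0.48) and MHC class II (-0.56) lists were called at adjusted p-values of 0.00424 and 0.0036 (0.631 and 0.608 with an estimated correlation). With slide as a block they were at -0.23 and -0.30 (adjusted p = 0.124 and 0.117) and within the slide at -0.35 (called, adjusted p = 0.019) and -0.31 (adjusted p = 0.124), and natural killer markers were not called without irradiated 2 (-0.37) and were at -0.28 without sham 2. Endothelial markers had a mean of -0.27 with 18 of 20 members negative and 0 past the threshold in limma (adjusted p = 0.00146; 0.26 with an estimated correlation; slide-blocked -0.31, within-slide -0.31). Tie1 was at -0.76 (adjusted p = 0.495; called without irradiated 2, at -1.05). Hepatocyte markers, which belong to another organ, had a mean of -1.50 in heart with all 13 negative (adjusted p = 5.43e-05; 0.631 with an estimated correlation; -1.41 with 1 gene at its bound). It was -0.04 with slide as a block, 0.04 within the slide and -0.62 without sham 1 (adjusted p = 0.0673). These transcripts were high on sham arrays 1 and 2, which lay on the slide of the liver arrays.

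In liver, 5 against 5 arrays, B cell genes fell most after the globins. Cd79b, a subunit of the B cell receptor, fell 12.1-fold (-3.60 ± 0.26, adjusted p = 2.63e-05). Ms4a1, which encodes CD20, and the transcription factor Spib were below background on every irradiated array, and were at least 9.14-fold (-4.73 ± 0.35, adjusted p = 2.63e-05) and at least 10.7-fold lower (-4.07 ± 0.34, adjusted p = 5.37e-05). Fcmr (-5.18 ± 0.39, adjusted p = 2.98e-05) and the inhibitory receptor Btla (-4.12 ± 0.34, adjusted p = 5.27e-05) were each above background on 1 of 5 irradiated arrays. Of 15 measured B cell markers 8 fell and 7 did not pass, and 11 fell adjusted over the list alone. The mean was -2.44 and the median -2.91, or -2.19 and -2.79 at the bounds (adjusted p = 1.16e-27; 0.0365 with an estimated correlation), and the slide-blocked mean was -2.11. The within-slide mean was -1.01, with most of these markers too dim to enter. Both liver slide fits rest on 1 sham array, sham 5, which also carried heart transcripts. Slide-blocked values were -3.01 for Cd79b, -4.48 for Ms4a1, -4.07 for Spib, -4.45 for Fcmr and -3.99 for Btla, and within the slide Cd79b was at -3.29.

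The T cell list was called lower in liver too, with 2 members past the threshold. Ccr7, the homing receptor of naive lymphocytes, changed by -3.01 ± 0.23 (adjusted p = 3.22e-05; slide-blocked -2.72, within-slide -2.86 at an adjusted p of 0.0527). Lef1, a transcription factor of naive T cells, changed by -2.04 ± 0.30 (adjusted p = 0.00598; slide-blocked -1.86 at an adjusted p of 0.313, within-slide -1.96 at 0.35). Of 18 measured members these 2 fell and 16 did not pass, with Cd2 at -1.53 (adjusted p = 0.0619; called without irradiated 1, at -1.74), and 13 fell adjusted over the list alone. The mean was -0.89 and the median -0.74 (adjusted p = 7.49e-16; 0.145 with an estimated correlation), slide-blocked -0.67 and within-slide -0.73. The natural killer list (-0.39, adjusted p = 6.06e-05) and the MHC class II list (-0.51, median -0.22, adjusted p = 0.00837) were lower too (0.479 and 0.631 with an estimated correlation) but were called in neither slide fit (-0.18 and -0.26, -0.19 and -0.13). The MHC class II list was not called without sham 4 (-0.45) or irradiated 2 (-0.29) either, and was at -0.79 without irradiated 5. The cell cycle list had a mean of -0.71 with 31 of 36 members negative (adjusted p = 3.99e-10; 0.608 with an estimated correlation). In limma 0 passed, over all genes or adjusted over the list alone, with Mki67 at -1.95 (adjusted p = 0.213). Its mean was -2.0 with slide as a block and -2.01 within the slide, and -0.45 without sham 5. Cardiomyocyte (-0.78, adjusted p = 0.00053) and fibroblast markers (-0.39, adjusted p = 0.00391) had like shifts (0.145 and 0.676 with an estimated correlation), slide-blocked -1.57 and -1.53. Cardiac transcripts were high on liver sham array 5, and the fibroblast list was not called without that array (-0.18) or irradiated 2 (-0.23).

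p53 target genes rose in liver as well. Phlda3 rose 7.51-fold (2.91 ± 0.25, adjusted p = 7.04e-05) and Eda2r 6.64-fold (2.73 ± 0.36, adjusted p = 0.00292). Ccng1, encoding cyclin G1, rose 2.75-fold (1.46 ± 0.18, adjusted p = 0.00247), Tnfrsf10b, the death receptor of TRAIL, by 1.75 ± 0.23 (adjusted p = 0.00288). Gdf15, a stress hormone, rose by 1.64 ± 0.21 (adjusted p = 0.00286) and Aen, an apoptotic nuclease, by 1.36 ± 0.15 (adjusted p = 0.000682). Mdm2, the ubiquitin ligase of p53 (0.86 ± 0.13, adjusted p = 0.00694), and Bax, a pore-forming apoptosis protein (0.87 ± 0.14, adjusted p = 0.0114), rose as well. Of 35 measured targets 14 rose and 21 did not pass, and 20 rose adjusted over the list alone. The largest change that did not pass was Cdkn1a at 2.84 ± 0.63 (7.17-fold, adjusted p = 0.0849), which was called without sham 3 (3.34, adjusted p = 0.00701). The list mean was 0.82 and the median 0.76, with 32 members positive (adjusted p = 2.21e-26; 0.0365 with an estimated correlation), slide-blocked 0.70 and within-slide 0.72. In the slide fits, which rest on sham 5, Phlda3 was at 2.70 and 2.96. The others were of like size there and not called. They were 2.95 and 3.14 for Eda2r, 1.36 and 1.49 for Ccng1, 1.56 and 1.72 for Tnfrsf10b and 1.23 and 1.21 for Gdf15. Values were 1.38 and 1.29 for Aen, 0.71 and 0.64 for Mdm2 and 0.94 and 0.82 for Bax (adjusted p = 0.0768 to 0.632). Bax lost its call without sham 1 (0.83, adjusted p = 0.0533) or sham 4 (0.82, adjusted p = 0.0572).

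Outside these lists, Gria3, a glutamate receptor subunit, rose in liver by 3.13 ± 0.40 (adjusted p = 0.00286; above background on 1 of 5 sham arrays; slide-blocked 2.81 at an adjusted p of 0.232, within-slide 3.38 at 0.0231). Atp8b5, a phospholipid flippase, rose by 1.62 ± 0.17 (adjusted p = 0.000545; 1.72 at 0.0561 and 1.82 at 0.0934), and its other probe was at 0.12. Ephx1 rose by 0.76 ± 0.08 (adjusted p = 0.000723; slide-blocked 0.87 at 0.0348, within-slide 0.84 at 0.0981). Cholesterol synthesis genes shifted up as a group, with 23 of 24 members positive and a mean of 0.37 (adjusted p = 1.67e-10; 0.311 with an estimated correlation; slide-blocked 0.28, within-slide 0.31). None rose over all genes and 10 rose adjusted over the list alone, with Sqle at 0.87 (adjusted p = 0.229) and Idi1 at 0.72 (adjusted p = 0.119; called without irradiated 3, at 0.83). Interferon response genes had a mean of 0.30 with 27 of 28 members positive (adjusted p = 8.25e-07; 0.519 with an estimated correlation; slide-blocked 0.31, within-slide 0.38). Of these 1 rose adjusted over the list alone, with Usp18 at 0.96 (adjusted p = 0.055; called without irradiated 3, at 1.11). Acute phase genes had a mean of 0.31 with 5 of 26 risen adjusted over the list alone (adjusted p = 2.04e-05; 0.503 with an estimated correlation; slide-blocked 0.41, within-slide 0.45). Saa2 was at 1.39 (adjusted p = 0.181) and Cxcl1 at 1.25 (adjusted p = 0.0965; called without irradiated 3, at 1.46).

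The other called lists in liver were small shifts, at adjusted p-values of 0.00491 to 0.0418 (0.311 to 0.853 with an estimated correlation). Calls in the slide fits rest on sham 5. Iron regulation (0.21) was at 0.27 and 0.26 there. Xenobiotic metabolism (0.26; 0.44 and 0.38 there) was not called without sham 5 (0.22) or irradiated 2 (0.24). Neural progenitor markers (-0.44; -1.14 and -1.43 there) were not called without sham 4 or 5 or irradiated 1, 2 or 5 (-0.46 to -0.30). Senescence genes (0.57, of which Gdf15 rose, and 5 rose and 1 fell adjusted over the list alone) were not called in the slide fits (0.25 and 0.23, adjusted p = 0.844 and 0.597). The integrated stress response list (0.21) turned there (-0.03 and -0.14) and was not called without sham 3 or 4 or irradiated 4 (0.12 to 0.20). Oxidative phosphorylation (0.08) was not called without sham 1 or 5 or irradiated 1 or 3 (0.03 to 0.06) or within the slide (0.08, adjusted p = 0.0692), but was with slide as a block (0.16). The NRF2 list (0.11, of which Ephx1 rose) was not called without sham 1 or irradiated 3 (0.07 for each) or in either slide fit (0.08 and 0.02, adjusted p = 0.214 and 0.465). Bile acid metabolism (0.13) lost its call without sham 3 or 5 or irradiated 2 or 5 (0.09 to 0.13) and with slide as a block (0.17, adjusted p = 0.14; within-slide 0.23, called), and lysosomal genes (0.09) theirs without sham 3, 4 or 5 or irradiated 2, 3 or 5 (0.06 to 0.11) and in both slide fits (0.07 and 0.09, adjusted p = 0.32 and 0.239).

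Spata18 did not pass the test in cerebellum or cerebrum and was at background in heart and liver. Its single probe was well above background on 5 sham and 4 irradiated arrays in cerebellum and on 3 and 4 in cerebrum, and on no array of heart or liver. Irradiated minus sham differences of mean log2 intensity were -0.03 in cerebellum, -0.17 in cerebrum, 0.27 in heart and -0.25 in liver, and the 2-sided exact permutation p-values were 0.921, 0.651, 0.548 and 0.524, of which those of heart and liver compare background signal. In limma the changes were -0.02 ± 0.27 in cerebellum (adjusted p = 0.994) and -0.17 ± 0.37 in cerebrum (adjusted p = 0.908). The cerebrum value was positive with slide as a block (0.24) and within the slide (0.21). Both brain values turned on leaving out 1 array, in cerebellum without sham 1 (0.20), sham 4 (0.03), irradiated 1 (0.08) or irradiated 4 (0.06) and in cerebrum without sham 3 or irradiated 5 (0.02 for each). The mean of the p53 target list, measured on the same arrays, was higher on every irradiated array than on every sham array of its tissue. It went from -0.40 ± 0.08 to -0.03 ± 0.07 (SD) in cerebellum, from -0.18 ± 0.06 to 0.12 ± 0.04 in cerebrum. It went from 0.81 ± 0.09 to 1.35 ± 0.16 in heart and from 0.08 ± 0.15 to 0.86 ± 0.19 in liver. The 2-sided exact permutation p was 0.00794 in each tissue, the smallest these group sizes allow. Of the mitophagy list, 26 members were measured in each brain region and 25 in heart and liver, and 0 passed in limma in any tissue, over all genes or adjusted over the list alone. The list mean was 0.01 in cerebellum (median -0.02, adjusted p = 0.357), 0.09 in cerebrum (adjusted p = 0.00827), 0.08 in heart (adjusted p = 0.274) and 0.06 in liver (adjusted p = 0.334). In cerebrum 22 of 26 members were positive, among them Tbk1 (0.26), Pgam5 (0.25) and Bnip3 (0.18, adjusted p = 0.792). The list there was not called with an estimated correlation (adjusted p = 0.479), with slide as a block (0.07, adjusted p = 0.076) or within the slide (0.04, adjusted p = 0.283).

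**Figure D4:**
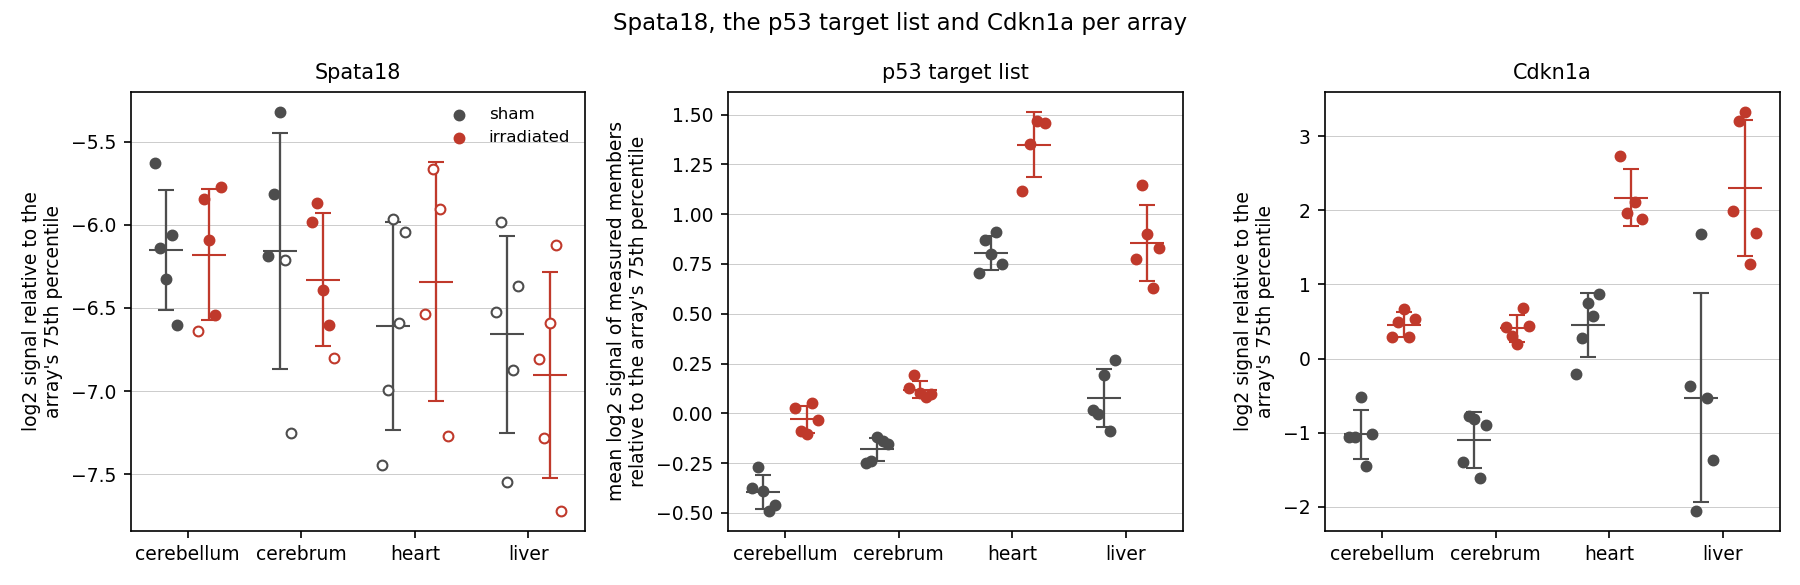
Normalised log2 intensity of Spata18 and the mean of the p53 target list on each array, by tissue and group, with filled Spata18 points well above background and open points not, bars at the mean and whiskers of 1 SD. Sham and irradiated arrays overlap for Spata18 (differences of -0.03, -0.17, 0.27 and -0.25) and are apart for the p53 list (0.37, 0.30, 0.54 and 0.78) in cerebellum, cerebrum, heart and liver.

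The tissues were then compared with each other, to find genes whose response to irradiation differed. The F test called 252 of 18992 genes, whose largest response lay in heart for 167, liver for 73, cerebellum for 10 and cerebrum for 2. It called 117 among genes measured in all 4 tissues and 159 with the left-out heart array back. Leaving out 1 mouse in all tissues gave 101 genes without sham 1, 117 without sham 3, 158 without sham 4, 147 without irradiated 3 and 167 without irradiated 5, and with slide as a block 188 were called, 60 of them shared. Mcm10 changed by -3.59 in heart (below background after irradiation, bound given above) and by -0.08, -0.07 and 0.16 in cerebellum, cerebrum and liver (adjusted p = 3.13e-10). The histone H2ac4 was at -5.00 in heart (likewise) against -0.45 to 0.47 elsewhere (adjusted p = 2.43e-08). H1f5, another histone, was at -3.48 in heart and -1.69 in liver against -0.17 and 0.01 in brain (adjusted p = 2.34e-07), and the cyclin Ccnb2 at -2.87 and -1.0 against 0.07 and 0.04 (adjusted p = 1.11e-05). Fcmr was at -5.18 in liver, -2.74 in heart (bound above, as for Mcm10), -0.44 in cerebellum and -0.03 in cerebrum (adjusted p = 1.11e-07). Phlda3 was at 2.91 in liver and 1.31 in heart against 0.38 in cerebellum and 0.29 in cerebrum (adjusted p = 2.71e-06). Gria3, by another probe than above, was at 3.45 in liver and 1.12 in heart against -0.04 and -0.05 (adjusted p = 5.31e-06; 0.0884 with slide as a block). The responses of Cdkn1a (adjusted p = 0.539), Eda2r (adjusted p = 0.272) and Hbb-bt (adjusted p = 0.468) were not shown to differ. By list, 15 of 40 measured cell cycle genes, 9 of 35 p53 targets, 7 of 16 B cell markers and 0 of 26 mitophagy genes differed. For mitophagy as for the other lists this count is limma's F test adjusted over all genes, in which 2344 genes had an unadjusted p under 0.05.

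A sex by irradiation interaction was tested in each tissue, since both groups held males and females. No gene passed in limma in any tissue, and 464 genes in cerebellum, 605 in cerebrum, 111 in heart and 2347 in liver had an unadjusted p under 0.05. Leaving out sham 1 gave 1 gene in cerebellum and 2 in cerebrum, and leaving out irradiated 5 gave 1 in cerebrum. In liver there were 4 without irradiated 3, 3 without irradiated 2, 2 without sham 4 and 1 without sham 1, sham 2 or irradiated 4.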

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

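The tests of explanations and the counts over other splits of the mice were chosen after the results they bear on had been seen.

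Hepatocyte transcripts stood high on sham heart arrays 1 and 2, which shared a slide with liver arrays. The 3 sham arrays of the other slide had list means of -2.28 to -1.62, inside the irradiated range of -2.83 to -0.89, against 1.93 and 1.13 on the 2 arrays. The change of -1.50 over all arrays thus rests on the 2 arrays. A comparison on the other slide leaves out these 2 arrays, which define the pattern. It can only show whether the remaining hearts differed by that much. Among the arrays of that other slide irradiated and sham hearts differed by -0.0814 ± 0.46 (SE, 3 sham and 4 irradiated arrays, with no sex term; 0.04 in limma with sex), 3.07 SE above the change of -1.50 over all arrays, a bound set after the value was seen in place of a round -1.0, which lay within 2 SE, so a smaller effect stays open. Liver RNA mixed into the 2 samples would bring all hepatocyte transcripts at 1 share of their liver level. The median share was 0.695% and 0.305%, but only 55% of the members, over both arrays, lay within 3-fold of it, so a mixture may account for part of the excess and stays open, as does the slide that these 2 arrays shared.

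Globin and Alas2 transcripts were lower in all 4 irradiated tissues. If less blood were left in irradiated tissues, platelet markers that came with blood alone would fall by as much, down to the background limit. Those well above background in sham had a median change of -0.32 over 27 pairs of marker and tissue (lowest -1.89). Medians were -0.37 in cerebellum, -0.25 in cerebrum, -1.40 in heart and -0.13 in liver. This argues against less blood as sole cause, unless tissue cells made these markers too (not tested). Slide layout is argued against in cerebellum and heart, where the 6 genes had mean changes of -5.39 and -5.88 among arrays of 1 slide (5 sham and 3 irradiated, 3 and 4). It stays open in liver (-5.99) and cerebrum (-6.54), where 1 array of a group shared the slide. A loss of young red cells that still hold globin RNA, if irradiation stops their supply from marrow, is a hypothesis not tested here.

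B cell markers were lower in irradiated liver. With slide as a block their mean change was -2.11. The 1 sham array on the slide of irradiated arrays had a list mean of -1.93. It lay in the sham range (-2.48 to -1.26), apart from the irradiated one (-4.57 to -4.26). That rests on 1 array, which also carried heart transcripts, so slide layout stays open. Platelet markers in liver changed little (median -0.13, lowest -0.43). Liver cells may make some of them too (not tested), as sham Clec1b was at 2.07 in liver and -1.10 in heart, so they cannot decide on less blood. A loss of B cells from irradiated liver stays a hypothesis beside slide layout and sampling, such as of attached lymphoid tissue (not tested).

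Chance alone sets an array apart in about 1 in 20 groups of this size, and 25 of 457 groups of arrays had 1, which were 1 of 16 groups for array measures, 8 of 128 for list means and 16 of 313 for genes. All values that follow are normalised log2 intensities unless marked otherwise, each standing apart from the other arrays of its tissue and group. Liver sham 1 had 51.9% of probes well above background, against 60.1% to 63.4% on the other 4. Cerebellum sham 2 stood above the rest for the MHC class II list (-2.21), the erythroid list (1.37), the microglia list (0.81), the fibroblast list (-0.26) and Slc2a5 (-2.22). Cerebrum sham 2 was high for the neutrophil list (-1.94), cerebrum irradiated 1 low for the monocyte list (-1.05), heart irradiated 3 low for the endothelial list (2.21) and liver sham 5 high for the fibroblast list (0.23). Among genes in brain, Ccng1 was low on cerebellum sham 4 (0.70) and Eda2r high on cerebrum irradiated 5 (-1.09). In heart, sham 2 was high for Hba-a1 (9.28), Hba-a2 (9.20), Btla (-2.41) and E2f2 (0.32), irradiated 2 for Tie1 (1.69) and Apoa2 (2.59), and irradiated 3 for Gp9 (-2.32). In liver, sham 2 was high for Alas2 (3.59), irradiated 1 for Irf7 (4.70) and irradiated 2 for Trp53inp1 (2.98), Atp8b5 (2.54) and Btla (-5.64), and irradiated 5 was low for Mdm2 (3.12).

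Responses differed between tissues by limma's F test for 252 genes, led by Mcm10 (adjusted p = 3.13e-10), H2ac4 (2.43e-08), Fcmr (1.11e-07), H1f5 (2.34e-07), Phlda3 and Zdhhc22 (2.71e-06 for both). Next came Gria3 (5.31e-06), Bend5 (6.6e-06), Spib (9.8e-06) and Ccnb2 (1.11e-05). Bend5 in liver and Spib outside it were too dim to be tested alone.

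Among data outside the comparisons, the heart array left out had a p53 list mean of 1.11, above the sham range of 0.70 to 0.91 and just below the irradiated range of 1.12 to 1.47. On it Mki67 (-2.93) and Cdkn1a (2.05) were within the irradiated range, whereas Hba-a1 (6.96), Hbb-bt (2.42) and Alas2 (-1.61) lay between the groups and the platelet genes Gp9 (1.37) and Clec1b (1.43) above every other heart array. Probes with no gene name were also tested, and limma called 21 of 15205 in cerebellum (1 higher, 20 lower), 2 of 14037 in cerebrum, 9 of 9260 in heart and 20 of 11570 in liver.

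Other splits of the 10 mice into groups of these sizes were drawn 100 times, the real one included. As many genes as the real split were called in 5 of the 100 splits in cerebellum (13 genes, highest other 2494). In cerebrum it was 2 (10, highest other 2819), in heart 2 (77, highest other 217) and in liver 1 (94, highest other 14). As many lists were called in 42 splits in cerebellum (10 lists, highest other 24) and 35 in heart (13, highest other 29). In cerebrum it was 2 (19, highest other 19) and in liver 1 (22, highest other 21). The 6 genes lower in all 4 tissues were matched by 1 split, the real one (highest other 0), and the 252 genes of the F test by 2 (highest other 684). Shares were under 0.05, unadjusted, except for genes in cerebellum and lists in cerebellum and heart. As other splits mixed irradiated and sham mice, no share here can exclude chance. Why some splits called several times the real count in cerebellum, cerebrum, heart and the F test was not tested. The split with 217 genes in heart and 684 in the F test put 4 females in its group of 5.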

How the results depend on the processing

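Alternatives marked above as added were chosen after the data had been seen.

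Array intensity was lowest in heart, where dim transcripts were measured least well, and Spata18 there and in liver was not well above background on any array. For that reason the alternatives gave a value for it in those tissues only without the filter on dim probes (0.25 in heart, adjusted p = 0.856, and -0.34 in liver, adjusted p = 0.788). Over all alternatives other than leaving out single arrays, 2446 values of named genes were recomputed. Direction and side of the threshold held in 2142, 263 fell short of the threshold with the direction kept, 30 passed it newly and 11 turned. Of 1022 values of called lists 736 held, 266 fell short and 20 turned. An estimated correlation between list members accounted for 59 of the 266. Of the 68 values of genes whose response differs between tissues, 66 held and 2 fell short. The sham and irradiated samples share only a replicate number. Same-numbered samples had a mean correlation of -0.15 in cerebellum, -0.08 in cerebrum, -0.10 in heart and 0.18 in liver (0.04, 0.02, 0.03 and -0.05 between other numbers), and it was over 0.1 in 1 of 5, 1 of 5, 0 of 4 and 4 of 5 pairs, so not every sample deviated with its own number. For the values below the cause was not tested, except that an alternative with fewer arrays or probes has less to test.

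With the replicate block 8 genes were called in cerebellum against 13, 7 in cerebrum against 10, 32 in heart against 77 and 44 in liver against 94. With slide as a block the counts were 0 in cerebrum, 42 in heart and 47 in liver, and 0 genes were shared by all 4 tissues against 6. Within 1 slide the count in heart was 27. With all tissues and slide in 1 fit the counts were 37 in cerebellum, 230 in heart and 264 in liver. Array weights gave 147 in cerebellum, 25 in cerebrum and 3037 in heart. Sex and age together gave 43 in heart and 60 in liver, and no sex term gave 50 in liver. Only probes above background on every array left 27 in heart, putting the left-out array back gave 51, and leaving out the 2 sham arrays with liver transcripts gave 27. Testing unnamed probes too gave 37 in cerebellum, and the files as attached gave 51 in liver. The F test called 159 genes with the left-out array back and 117 among genes measured in all 4 tissues, against 252. The authors' deposited values gave 1 gene for the sex interaction in liver against 0.

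Lists called were 4 with sex and age and 6 with array weights in cerebellum against 10, 12 with normexp in cerebrum against 19, and 22 with the files as attached in heart against 13. In liver they were 14 with normexp, 13 with quantile normalisation and 14 with the files as attached, against 22. An estimated correlation left 0, 0, 0 and 2 lists in cerebellum, cerebrum, heart and liver, and the p53 list fell short with it in the first 3 at unchanged means of 0.37, 0.31 and 0.54. Its means lay between 0.33 and 0.40, 0.29 and 0.33, 0.48 and 0.63, and 0.75 and 0.88 when any 1 array was left out, called each time.

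Spata18 turned positive in cerebellum (-0.02) with quantile normalisation (0.17), the authors' values (0.0342), sex and age (0.0658) and array weights (0.12). In cerebrum (-0.17) it did so with normexp (0.10), quantile normalisation (0.0627), the authors' values (0.015), slide as a block (0.24), 1 slide (0.21) and all tissues in 1 fit (0.28). In cerebrum the same 3 slide settings, in that order, turned the choroid plexus list (0.62, 0.40 and 0.68), the oligodendrocyte list (0.22, 0.13 and 0.23), the pancreas list (0.0493, 0.13 and 0.16), Sesn2 (0.19, 0.25 and 0.21), Ttr (0.58, 0.37 and 0.70) and Kcne2 (0.77, 0.41 and 0.87). The oxidative phosphorylation list there turned within 1 slide (-0.0205) and with all tissues in 1 fit (-0.00999), and Bnip3 within 1 slide (-0.0206). In heart the acute phase list turned with the authors' values (-0.0134), without the filter on dim probes (-0.10) and with the left-out array back (-0.0428). The hepatocyte list turned within 1 slide, which leaves out the same 2 sham arrays as the added alternative (0.0362 in both), and Ccng1 with the left-out array back (-0.0112). In liver the xenobiotic list was at -0.000951 without a sex term and with the replicate block, and the integrated stress response list at -0.0257 and -0.14 in the slide fits.

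Leaving out 1 array at a time gave 9 to 34 genes and 5 to 16 lists in cerebellum, 9 to 11 genes and 16 to 23 lists in cerebrum, 46 to 331 genes and 13 to 19 lists in heart, and 56 to 98 genes and 17 to 25 lists in liver. The shared genes numbered 5 to 7 and those of the F test 101 to 351. Interaction counts were 0 to 1 in cerebellum, 0 to 2 in cerebrum and 0 to 4 in liver. Spata18 lay between -0.16 and 0.20 in cerebellum and between -0.42 and 0.0208 in cerebrum, and the acute phase list in heart between -0.17 and 0.49. Of 1500 values of named genes 1371 held, 115 fell short and 14 newly passed, and of 588 values of lists 504 held, 82 fell short and 2 turned.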

Other observations

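The tests below were planned, but the genes were chosen after their values had been seen, except Alas2, Inka2, Psrc1, Ddit4l, Fcer2a and Rad51b, Zdhhc22 and Ces2e in heart and Btla in liver, which the naming rule gave.

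Besides the globins, 3 single genes known from red cell precursors fell in heart. Slc4a1, which encodes the anion exchanger band 3 of the red cell membrane, was below background on every irradiated array and at least 3.65-fold lower (-3.40 ± 0.47, adjusted p = 0.00672; slide-blocked -3.07). E2f2, a cell cycle transcription factor that acts in red cell formation, changed by -2.93 ± 0.32 (adjusted p = 0.00124; slide-blocked -2.62, within-slide -2.68). Slc25a37, the mitochondrial iron importer of erythroblasts, changed by -1.14 ± 0.18 (adjusted p = 0.0168). It was at -0.99 with slide as a block and -1.0 within the slide (adjusted p = 0.127 and 0.183), and its call was lost without sham 1 or 5 or irradiated 3 or 5 (-1.17 to -1.02). All 4 irradiated arrays lay below every sham array for each of these genes. Responses differed between tissues for Slc4a1 (F test, adjusted p = 0.0413), Slc25a37 (0.00731) and E2f2 (0.00217). Slc4a1 was at -0.32 in cerebellum, -1.40 in cerebrum, -2.77 in liver and -3.40 in heart (at least 3.65-fold). Alas2 also differed (adjusted p = 0.0004), with -2.20 in liver against -7.09 to -5.70 elsewhere.

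Several genes outside the lists were called in both heart and liver. Zdhhc22, a palmitoyltransferase, was at -4.92 ± 0.31 in heart and -1.95 ± 0.26 in liver (adjusted p = 7.68e-06 and 0.00299), Slc6a20a, an amino acid transporter, at -3.08 and -1.93 (adjusted p = 0.000166 and 0.0437). Btla was at -2.95 in heart, where it was below background on every irradiated array and at least 1.82-fold lower, and at -4.12 in liver (adjusted p = 0.0168 and 5.27e-05). Ces2e rose in both (2.09 and 0.96, adjusted p = 0.000473 and 0.026). With slide as a block the heart values of Zdhhc22 (-4.67), Slc6a20a (-2.90) and Ces2e (2.16) were called, as was Btla in liver (-3.99). Btla in heart (-2.65) and the liver values of Zdhhc22 (-1.78), Slc6a20a (-1.68) and Ces2e (0.89) were not (adjusted p = 0.119 to 0.674). Within the slide Zdhhc22 (-4.67), Slc6a20a (-2.91) and Ces2e (2.15) were called in heart, and the liver values of Zdhhc22 (-2.15), Slc6a20a (-2.30) and Ces2e (0.95) were not. Leaving out sham 4 or 5 or irradiated 3 or 5 ended the call of Btla in heart (-3.0 to -2.67). In liver Ces2e was not called without sham 1, 2, 3 or 4 or irradiated 2 or 5 (0.89 to 1.01), nor Slc6a20a without sham 3, 4 or 5 or any 1 irradiated array other than irradiated 3 (-2.15 to -1.63). Over the 4 tissues the responses of Zdhhc22, Slc6a20a and Btla differed (F test, adjusted p = 2.71e-06, 0.000627 and 0.00639), and that of Ces2e was not shown to differ (adjusted p = 0.711). In brain Btla was too dim to be tested, and Zdhhc22, not called there, was at -2.06 ± 0.31 in cerebellum and -0.74 in cerebrum.

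Single genes of growth arrest and DNA repair rose in liver, of which Psrc1, Ddit4l, Polk, Zmat3 and Btg2 belong to the p53 target list. The DNA repair list was not called there (mean -0.09, adjusted p = 0.539), and of its 42 measured members Apex1 alone rose. Inka2, an inhibitor of p21-activated kinases, was below background on every sham array and at least 1.49-fold higher after irradiation (2.81 ± 0.45, adjusted p = 0.0127). Psrc1, a microtubule protein, rose by 2.20 ± 0.37 (adjusted p = 0.0176) and Ddit4l, an inhibitor of mTOR signalling, by 1.59 ± 0.30 (adjusted p = 0.0394). The translesion polymerase Polk was at 1.15 ± 0.16 (adjusted p = 0.00482), the RNA-binding protein Zmat3 at 1.04 ± 0.18 (adjusted p = 0.0193), the antiproliferative gene Btg2 at 1.02 ± 0.18 (adjusted p = 0.0255), the base excision nuclease Apex1 at 0.69 ± 0.13 (adjusted p = 0.0425) and the alkylation repair gene Mgmt at 0.65 ± 0.11 (adjusted p = 0.0217). In heart Rad51b, a recombination gene, rose (1.15 ± 0.21, adjusted p = 0.0386). None of these 9 was called with slide as a block (3.01, 1.15, 1.36, 0.98, 0.71, 0.76, 0.56, 0.61 and 1.04 in that order, adjusted p = 0.253 to 0.865) or within the slide (3.52, 1.33, 1.43, 1.04, 0.72, 0.77, 0.46, 0.57 and 1.05, adjusted p = 0.0625 to 0.821). Psrc1 was not called without sham 4 or irradiated 2 (2.06 and 2.07), Zmat3 without sham 1, 2 or 4 or irradiated 1 or 2 (0.94 to 1.04), Mgmt without sham 1, 2 or 3 or irradiated 2, 3 or 5 (0.57 to 0.68), and Btg2 without sham 1, 2, 3 or 4 or irradiated 2, 3 or 5 (0.97 to 1.08). Ddit4l held only without sham 1 or irradiated 4 or 5 (otherwise 1.26 to 1.64), Apex1 only without irradiated 1 (otherwise 0.58 to 0.74) and Rad51b only without sham 3 or irradiated 2 (otherwise 1.06 to 1.23). The response differed between tissues for Inka2 (adjusted p = 0.000287), Zmat3 (0.000841), Apex1 (0.00232), Polk (0.0121), Rad51b (0.0195) and Mgmt (0.0425), and was not shown to differ for Btg2 (0.237), Ddit4l (0.155) or Psrc1 (0.157).

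Further single genes of lymphocytes, not tested as a group, were called lower in irradiated liver. Ccr6, of B cells and helper T cells, was at -2.20 ± 0.35 (adjusted p = 0.0113), Ccr9, of gut-homing lymphocytes, at -2.10 ± 0.34 (adjusted p = 0.0121) and Il7r, of naive T cells and lymphoid precursors, at -1.71 ± 0.21 (adjusted p = 0.00151), while the B cell IgE receptor Fcer2a was at -3.94 ± 0.51 (adjusted p = 0.00286). Slide-blocked values were -2.18, -1.91, -1.65 and -2.93, of like direction and not called (adjusted p = 0.136 to 0.396), and the within-slide values were -2.54 for Ccr6 and -1.74 for Il7r (adjusted p = 0.216 and 0.197). Ccr6 and Ccr9 were not called without irradiated 2 (-2.16 and -1.87). The responses of these receptors differed between tissues (F test, adjusted p = 0.00454 for Ccr6, 0.0178 for Ccr9, too dim in heart to be tested there, and 0.0464 for Il7r).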
